A study of Mus musculus with 2 samples.

How the data were processed

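The data are ATAC-seq peak lists from mouse regulatory T (Treg) cells. ATAC-seq marks open chromatin through the insertion of sequencing adapters by the Tn5 transposase. Per the labels, CD4+CD25+YFP+ cells were sorted from spleen and lymph node of female C57BL/6 mice aged 7 weeks, 50000 cells went into the reaction, and libraries were made with a Nextera XT kit and sequenced on a NovaSeq instrument. Of the 2 libraries, 1 came from Foxp3-Cre mice with intact Tkt (WT Treg, replicate 1) and 1 from Foxp3-Cre mice with floxed Tkt (TKT cKO Treg, replicate 1). Groups were taken from the sample titles and genotype labels.

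Per the submitters' processing notes, Trimmomatic, FastQC, BWA and MACS2 were used and the genome build was mm10. Tool versions, peak caller settings, duplicate removal, mitochondrial read removal, any shift of reads for the Tn5 insertion offset, the use of a blacklist and the annotation tool are not given in the sources used here. Each deposited list holds the peaks of 1 library, so peaks were called per library and not on pooled reads. For each peak the authors gave its position, width, a score, an annotation class, the gene assigned to it, a transcript and the distance to its transcription start site (TSS). The score column, deposited by the authors, is not named further by the file headers. Its lowest value was 1.31 in the WT list and 1.34 in the cKO list, just above the 1.30 that is −log10 of 0.05, but its meaning was not stated, so it is called a score here. A score of this kind moves with sequencing depth. It was used only to rank and filter peaks within their own list, apart from 1 setting, described with the others below, that applied a common minimum. The 1 gene per peak was the authors' choice and includes predicted gene models. Peaks within 3 kb of a TSS carried the promoter class in the authors' annotation. Coordinates are those of the deposited lists, counted from 1, in mm10.

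Read totals were not used here, so the depth of each library is unknown, and a missing peak cannot be told from a peak that fell below the caller's threshold. Intervals on shares are Wilson 95% intervals (Newcombe for differences of shares) and cover counting error only, because neighbouring peaks and PCR copies are not independent. Where a share was 0, the limit given is 3 counts of the total. There is 1 library per group. No difference between the groups has a replicate check, and no p-value is given.

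A WT peak counted as shared when a cKO peak overlapped it by at least 1 bp, and the reverse for cKO peaks. Chance overlap was measured by moving the cKO peaks by 1, 2 and 5 Mb. Shares were taken over all peaks, by annotation class and by 10 equal score bins within each list, and the gap between promoter and other peaks was also taken within score bins and within score and width bins. Genes with a promoter peak were counted by the symbols assigned by the authors. For 17 gene lists fixed before the data were examined, the share of WT peaks overlapped by a cKO peak was ranked among 10000 random lists. Random lists matched each member on a class of its number of WT peaks and on the tertile of its strongest WT score. Genes with many peaks were pooled in 1 class, so their exact numbers were not matched. The random genes came from all symbols with a WT peak, predicted models included. A list was called apart when it lay outside the central 95% of the random lists, which describes these libraries and is not a test of the genotypes. For each list, a like-peak share was also computed as the mean share of WT peaks in the same class and the same of 20 equal score bins, with and without matching on 4 width bins.

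The genes named were chosen by a rule fixed before the data were examined. It took Tkt, as the targeted gene; 12 core Treg genes; the 10 genes with the highest scoring WT peaks without a cKO overlap and the 10 with the highest scoring cKO peaks without a WT overlap; the 5 genes with most unshared peaks in each library, ties kept; and in each list up to 2 members with the highest scoring unshared WT peak and up to 2 with most shared peaks. Predicted models were passed over in the rankings outside the lists. Members without a cKO peak, or named otherwise, were chosen after their values were seen, and so were 18 gene families and 1 further list of Treg activation markers in the closing section.

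The overlap code was compared with bedtools 2.31.1 over 34440 peaks and differed at 0 of them in each of the 3 overlap definitions. The list ranking was tested on simulated data. Of 100 random lists of 36 genes with no change, 99 were called within the band, of 100 lists with overlap lowered by 15 points 80 were called below it, and of 100 lists with overlap raised by 15 points 56 were called above it. Simulated overlap in these lists was kept between 0 and 100%. Strong peaks, mostly shared already, therefore rose by less than 15 points, and the weakest peaks fell by less. Lists of other sizes were not simulated, so these recovery rates do not describe the shorter lists. For the 7 B cell markers with a WT peak the band ran from 18.2 to 70.0%, and a call inside so wide a band says little. A promoter gap of 5 points simulated within strata was recovered as 5.34. Analyses ran in Python 3.11.15 with pandas 2.3.3, NumPy 2.4.6 and SciPy 1.17.1, and figures were drawn with matplotlib 3.10.9.

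Alternatives fixed before the data were examined were a stricter and a looser overlap, the upper part of each list by score, equal numbers of peaks, a common score minimum, merged neighbouring peaks, autosomes only, a promoter window of 1 kb, a TSS window of 10 kb for the lists, and matching on peak number only. Alternatives added later were WT peaks at least as wide as the narrowest cKO peak, gene assignment by RefSeq gene bodies (GRCm38.p6, the same primary assembly as mm10) with a margin of 10 kb, lists without promoter peaks, and lists without their member with most WT peaks. A planned search for transcription factor motifs in the peaks needs the genome sequence and was not run.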

Results

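Open chromatin was compared between Treg cells with and without transketolase (Tkt), an enzyme of the non-oxidative branch of the pentose phosphate pathway. Treg cells are CD4 T cells that express the transcription factor Foxp3 and restrain immune responses. The mice carried a single Foxp3-Cre allele, described as chimeric in the labels, and Cre-expressing cells were sorted by YFP. The series title places the comparison within a study of how this pathway controls Treg function. There was 1 library for each genotype, so every difference below compares those libraries and none could be set against the spread between replicates. The WT list held 34440 peaks that covered 36.0 Mb, and the cKO list held 19680 peaks that covered 20.7 Mb, a ratio of 1.75 in number and 1.74 in length. Median widths were 977 and 974 bp. The narrowest peak had 360 bp in the WT list and 465 bp in the cKO list. Sequencing depth was unknown, and the number of called peaks moves with it.

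The targeted gene was examined first. Tkt had 1 peak in each library, at its promoter on chromosome 14, at 30548526 to 30550010 in WT and 30548665 to 30550036 in cKO. Within their own lists these peaks lay in score bin 9 of 10 (WT) and 7 of 10 (cKO), where bin 10 holds the highest scores. Both peaks span the TSS. The labels do not say whether the floxed part of Tkt includes this region, so the peaks check nothing about the genotype labels.

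The core Treg genes had called peaks in the cKO library. All 12 genes examined had at least 1 cKO peak, and 34 of their 47 WT peaks were overlapped by a cKO peak (72.3%, 95% interval 58.2 to 83.1). Foxp3, the lineage-defining factor, had 2 peaks in each library, both shared, at X 7579609 to 7580481 and X 7583208 to 7584740 in WT. Entpd1, which encodes the ectonucleotidase CD39, shared 4 of 4 WT peaks, and Tgfb1 and Icos shared their only WT peak. Il2ra, the high-affinity IL-2 receptor chain, shared 4 of 6, and its unshared peaks lay in intron 1 at chromosome 2, 11654972 to 11655610 and 11657569 to 11657953. Ikzf2 shared 6 of 7, Ctla4 3 of 4, Itgae 3 of 4, Nt5e 3 of 5 and Tigit 1 of 2. Il10 shared 4 of 6, with its promoter peak among the shared ones and unshared peaks 19394 and 16166 bp upstream of the TSS. Lag3 was the core gene with most unshared WT peaks, at 3 of 5, which included both of its peaks of the promoter class. The 3 unshared Lag3 peaks were 368, 408 and 412 bp wide, narrower than any peak in the cKO list. No cKO peak assigned to these 12 genes lacked a WT partner. With both partners required to lie above the median score of their own list, Ikzf2, Lag3, Nt5e and Itgae had 0 shared peaks, because their cKO peaks all scored below the cKO median of 16.6, while Foxp3, Ctla4 and Il10 had 1 each, and Il2ra and Entpd1 had 2 each.

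**Figure D1:**
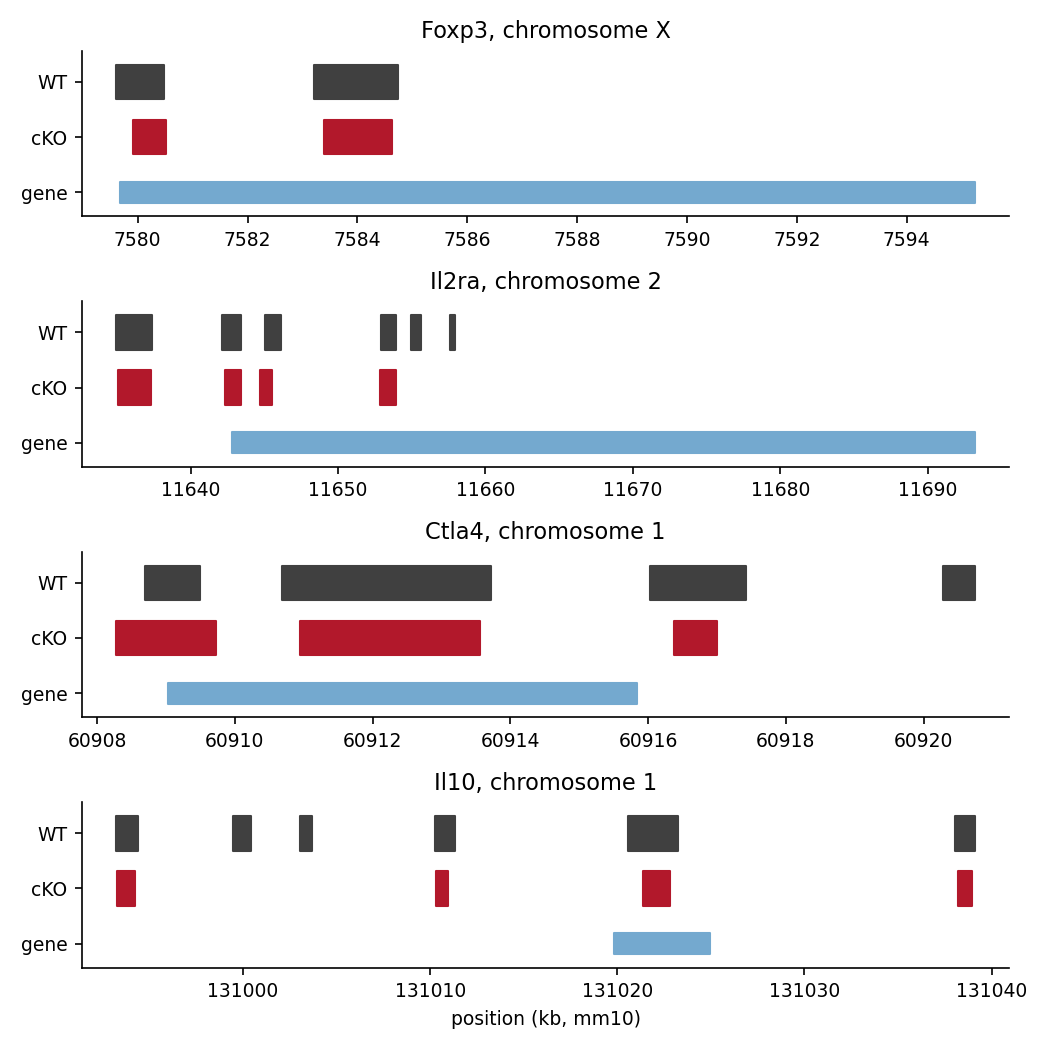
Called peaks at Foxp3, Il2ra, Ctla4 and Il10 in the WT library (dark bars) and the cKO library (red bars), with the span of the transcripts named in the deposited lists (blue), against position in kb (mm10). Foxp3 shows 2 peaks in each library, Il2ra 6 and 4, Ctla4 4 and 3, and Il10 6 and 4.

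Across the genome, most regions called in cKO cells were also called in WT cells, and the reverse held for little more than the stronger WT peaks. A WT peak overlapped 19216 of the 19680 cKO peaks (97.6%, 97.4 to 97.8), and a cKO peak overlapped 19313 of the 34440 WT peaks (56.1%, 55.6 to 56.6). Overlaps were nearly 1 to 1, so the shorter cKO list limits the WT share. The 56.1% therefore follows mostly from the 97.6% and the lengths of the lists. With the cKO peaks moved by 1, 2 or 5 Mb, the WT share was 2.44%, 2.04% and 1.71%. Promoter peaks were shared more often than others, at 74.3% of 15339 (73.6 to 75.0) against 41.4% of 19101 (40.7 to 42.1). Introns and distal intergenic regions stood at 39.8% and 42.9%. The WT share rose with each of the 10 equal score bins, from 6.68% in bin 1 through 47.0% in bin 5 to 99.5% in bin 10. On the cKO side 83.5% of the lowest bin was shared, and in each of bins 7 to 10 0 of 1968 peaks lacked a WT partner, which allows up to 0.152%. With the WT list reduced to the strongest 19680 peaks, 83.0% of WT peaks and 83.0% of cKO peaks were shared.

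**Figure D2:**
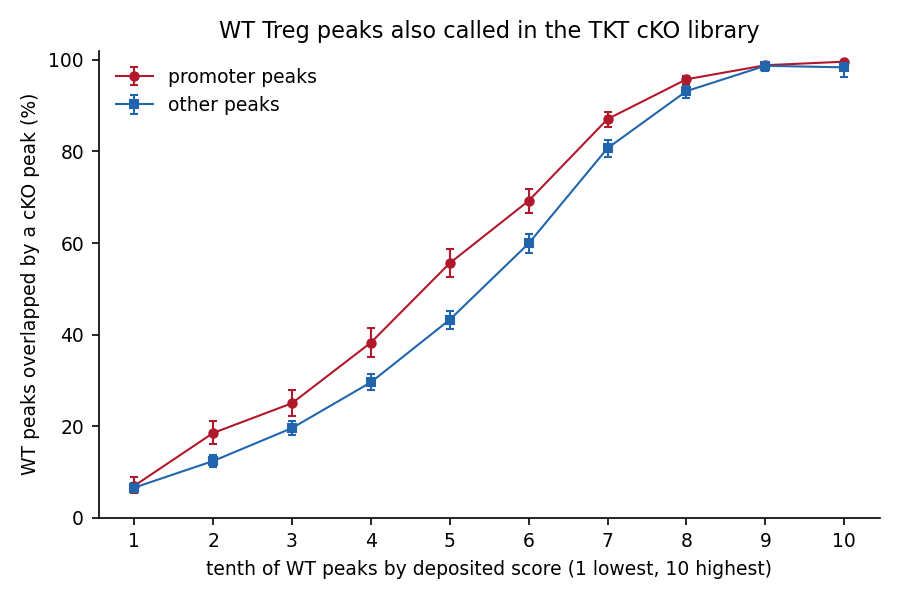
Share of WT peaks overlapped by a cKO peak (%) against 10 equal bins of the deposited WT score, for promoter peaks (red) and other peaks (blue), with 95% Wilson intervals. In bin 5 55.6% of promoter peaks and 43.3% of other peaks were shared, and in bin 10 99.6% and 98.4%.

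The gap between promoter and other WT peaks was 32.9 points (32.0 to 33.9). Promoter peaks had a median score of 69.9 against 17.6 for the others. Within score bins the gap was 5.70 points (4.81 to 6.59), and within bins of score and width it was 3.85 points (3.03 to 4.67). Promoters in the strict sense, within 1 kb of a TSS, were shared at 79.8%, whereas peaks 1 to 2 kb and 2 to 3 kb away were shared at 45.0% and 39.2%, close to introns. Median scores of these groups were 86.8, 18.3 and 17.2. This split was not taken within score bins, so an effect of distance cannot be told from peak strength. Promoter peaks made up 44.5% of the WT list and 57.8% of the cKO list. Within the WT list they rose from 803 of 3444 peaks in score bin 1 to 3136 of 3444 in bin 10. A shorter list of stronger peaks therefore holds a larger promoter share, and these 2 shares do not show a shift towards promoters in the knockout.

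At the gene level, 10623 genes had a promoter peak in both libraries, 3171 in WT alone and 181 in cKO alone. These classes follow the assigned symbol and class. For 122 of the 181 genes the cKO promoter peak overlapped a WT peak, and for 165 of the 3171 genes the WT promoter peak overlapped a cKO peak. With equal numbers of peaks, 1006 genes had a promoter peak in WT alone and 899 in cKO alone.

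In the upper 2 score bins 43 of 58 WT peaks without a cKO partner and 5758 of 6830 shared ones lay at promoters, and in bin 9 alone 31 of 41 and 2634 of 3403. Predicted models aside, the 10 genes with the highest scores were Gtpbp4, Rhbdd2, Aars2, Rrbp1, Art2b, Rab11fip5, Eloa, Ctnnbl1, Nol12 and Hdgf, and the peak lay at the promoter in all except Gtpbp4, whose peak on chromosome 13 at 9011704 to 9012168 lay in an intron of a predicted gene. Aars2 encodes the mitochondrial alanyl-tRNA synthetase, and its peak on chromosome 17 at 45506670 to 45507314 was its only WT peak. Rrbp1 and Eloa had 3 WT peaks each and no cKO peak. Art2b, an ADP-ribosyltransferase of the T cell surface, had 5 WT peaks, of which 1 was shared. These 10 peaks were between 380 and 1017 bp wide. Of the 58 strong peaks without a partner, among 6888 in all, 56 lay in the narrowest of 4 equal width bins (368 to 1092 bp). The 58 peaks had a median width of 683 bp, against 1287 bp for the 6830 shared ones.

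**Figure D3:**
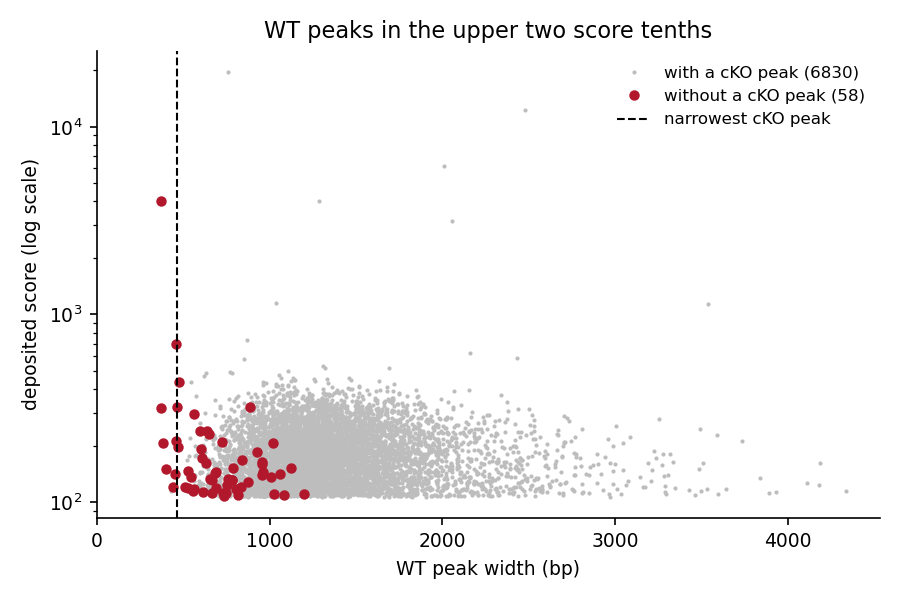
Deposited score (log axis) against width in bp for the 6888 WT peaks in the upper 2 score bins, with a cKO partner (grey, 6830) or without (red, 58). The dashed line marks the narrowest cKO peak, 465 bp, and the red points lie at or below 1200 bp.

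The genes with most unshared WT peaks were genes with many peaks. Mllt3, a subunit of the super elongation complex, had 13 unshared of 15 WT peaks, Pabpc2 12 of 13 and Sgms1, a sphingomyelin synthase, 11 of 19. Ipcef1 (of 13 peaks), Rora (18), St6gal1 (18) and Tox (19) had 10 unshared peaks each. Rora and Tox encode transcription factors with roles in T cells. Peaks found in the cKO list alone numbered 464, with 0 in score bins 7 to 10, 1 in bin 6, at the small nucleolar RNA gene Snora41, and 3 in bin 5. Apart from predicted and small RNA genes, the 10 leading genes (Lyz2, Pold4, Cd2ap, Csk, Rsg1, H2af-ps, Apba2, Ap3m1, Erbb2 and Dip2c) had peaks in score bin 3 or 4 of the cKO list. Lyz2, the lysozyme gene of myeloid cells, had no WT peak and 1 cKO peak, in its 3' UTR on chromosome 10 at 117277412 to 117278078. Csk, an inhibitor of Src-family kinases, had a cKO peak at its promoter on chromosome 9 at 57645179 to 57645896, beside 3 shared peaks. Most unshared cKO peaks per gene were 3, at Btbd35f29 and at Mitf, followed by 2 each at AC166114.1, Apba2, Ccnd3, Kdm2b, Sgms1, Speer4d and Trpm8.

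Among the 17 fixed gene lists, genes of the naive and central T cell state were shared more often than matched random lists, and genes silent in lymphocytes less often. The call for genes silent in lymphocytes held in only 5 of 10 alternative settings, and that for the naive and central list in 9 of 10. The other 15 lists lay within the central 95% of their random lists, though with matching on peak number only the lists of transcription factors, T cell receptor signalling, glycolysis, the TCA cycle and the cell cycle lay above it. With 17 lists, 0.85 would be expected outside this band by construction. For the naive and central list, 84 of 117 WT peaks had a cKO partner (71.8%, 63.0 to 79.2), against a median of 54.3% and a central 95% of 43.1 to 65.3 in random lists (percentile 99.96). All 17 of its members with a WT peak had a cKO peak. The same held for T cell receptor signalling (28 of 28), glycolysis (25 of 25) and housekeeping genes (15 of 15), whose lists lay inside their bands. Foxp1, a factor of T cell quiescence, shared 22 of 31 peaks, Bach2, which restrains effector differentiation, 11 of 14, Klf2, which drives the homing receptors, 7 of 8, and Ccr7, the lymph node homing receptor, 9 of 14. Tcf7 shared 5 of 6, and Lef1 and Bcl2 all of theirs (2 and 3). The strongest unshared WT peaks of this list lay 11425 bp from the Klf2 TSS and 35448 bp upstream of Tcf7. Restricted to peaks within 10 kb of a TSS the list shared 77.6%, against a median of 63.3% in random lists, at percentile 97.4, inside the band. Its members overlapped the transcription factor list by 5 genes.

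**Figure D4:**
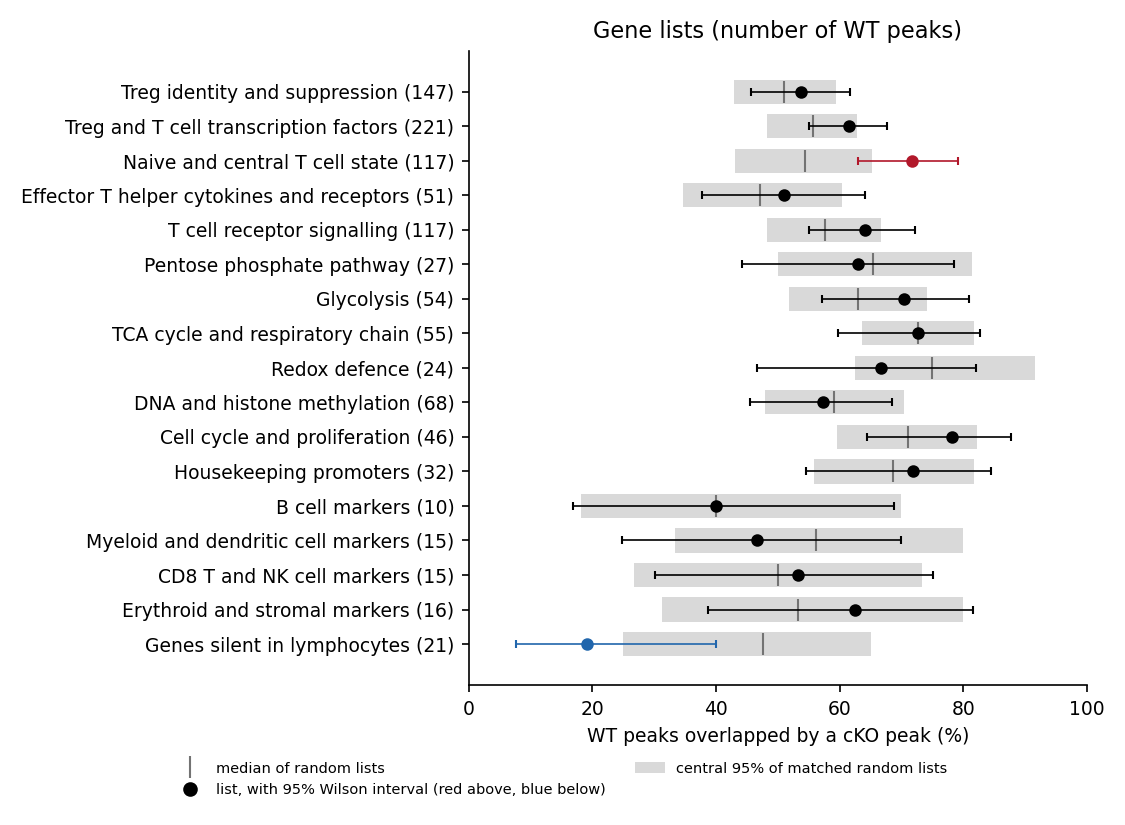
Share of WT peaks overlapped by a cKO peak (%) for each of the 17 lists (points, with 95% Wilson intervals and the number of WT peaks in brackets), over the central 95% of 10000 matched random lists (grey bars) and their median (ticks). The naive and central list lies above its bar at 71.8% and the list of genes silent in lymphocytes below it at 19.0%.

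Treg identity and suppression genes shared 79 of 147 WT peaks (53.7%, 45.7 to 61.6, percentile 73.6). Of the 36 members with a WT peak, 6 had all of them shared, 24 some and 6 none. Tnfrsf1b, encoding the TNF receptor TNFR2, shared 7 of 9 peaks and Ikzf2 6 of 7. The members without any cKO peak were Fgl2 (6 WT peaks), Klrg1 and Havcr2 (4 each), Il1rl1 (3), and Ebi3 and Socs2 (1 each), and their strongest WT peaks scored between 10.3 and 32.3, against a median of 28.1 for all WT peaks. Fgl2 encodes a secreted suppressive protein, and Klrg1 and Il1rl1 (the IL-33 receptor ST2) mark activated and tissue Treg cells. The strongest unshared WT peak of the list lay 5229 bp upstream of Capg on chromosome 6 at 72538329 to 72539162, and the next at the promoter of Cd83. Treg and T cell transcription factors shared 136 of 221 peaks (61.5%, percentile 94.1), with Bcl11b at 12 of 21. Unshared peaks of this list included 1 in an intron of Stat5b on chromosome 11 at 100814446 to 100815182. T cell receptor signalling genes shared 75 of 117 (64.1%, percentile 91.4), with 9 of 13 at Fyn and 6 of 10 at Dusp5. Effector T helper genes shared 26 of 51 (51.0%, percentile 72.1). Cxcr5 shared 5 of 8 and Il4ra 3 of 3, while Il18r1 and Il18rap, subunits of the IL-18 receptor, had unshared peaks in an intron and at the promoter.

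Metabolic lists lay inside the bands of genes matched on peak number and score. Pentose phosphate pathway genes shared 17 of 27 WT peaks (63.0%, 44.2 to 78.5, percentile 38.7), and 13 of the 14 members with a WT peak had a cKO peak, among them Taldo1, G6pdx and Pgd. Rpia, the ribose 5-phosphate isomerase, shared 4 of 5 peaks and H6pd 2 of 4. Glycolysis genes shared 38 of 54 (70.4%, percentile 90.5), with all 3 peaks of Pfkfb3 and 3 of 4 at Pdk1 shared, and unshared peaks near Pfkl and Pkm. TCA cycle and respiratory chain genes shared 40 of 55 (72.7%, percentile 48.3). Idh1 and Mdh2 shared 2 of 2 each, and the strongest unshared peak was at the Idh3b promoter. Redox defence genes shared 16 of 24 (66.7%, 46.7 to 82.0, percentile 8.27). The 4 redox members with a WT peak and no cKO peak were Gclm, a subunit of the rate-limiting enzyme of glutathione synthesis, Hmox1, Srxn1 and Prdx2. Sesn2 shared both of its peaks. DNA and histone methylation genes shared 39 of 68 (57.4%, percentile 37.1), with 5 of 7 at Kdm2b, 4 of 6 at Dnmt3a and an unshared promoter peak at Mbd2. Cell cycle genes shared 36 of 46 (78.3%, percentile 89.1), with 7 of 8 at Ccnd3 and an unshared promoter peak at Mcm2. With peaks assigned within 10 kb of RefSeq genes, the cell cycle list stood above its band at percentile 99.1. Housekeeping genes shared 23 of 32 (71.9%, percentile 69.5), with 4 of 6 at Ywhaz and 3 of 6 at Actb.

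Markers of other cells, most of which the CD4+CD25+YFP+ gate would remove, gave between 10 and 16 WT peaks and between 4 and 11 cKO peaks per list. No WT peak was assigned to 9 of 16 B cell markers and 10 of 20 myeloid and dendritic markers. The same held for 7 of 15 CD8 T and NK markers and 11 of 18 erythroid and stromal markers. Shared peaks in the upper 2 WT score bins lay at Cebpb, Tyrobp, Klf1, Klrb1c, Adgre1 and Pecam1. Lyz2, Gzma and Gata1 had 1 peak each in the cKO list alone. B cell markers had 10 WT peaks, of which 4 were shared (40.0%, percentile 43.0), with Cd79a and Pou2af1 shared and 4 unshared peaks at Cd79b. Myeloid and dendritic markers shared 7 of 15 (46.7%, percentile 20.3), with Cebpb and Adgre1 shared and the Spi1 peak unshared. CD8 T and NK markers shared 8 of 15 (53.3%, percentile 64.8), with 2 of 4 at Klrb1c. Erythroid and stromal markers shared 10 of 16 (62.5%, percentile 73.9), with 5 of 7 at Pecam1. Genes silent in lymphocytes shared 4 of 21 (19.0%, 7.67 to 40.0, percentile 0.33), against 47.6% in random lists. WT peaks of like score and class gave 36.8%, inside its interval, and with width matched 40.9%, just above it. Of these 21 peaks, 10 were assigned to Apoa1, the strongest unshared one 59266 bp from its TSS, and 3 to Neurog2. Without Apoa1 the list shared 18.2%, against a median of 36.4% in random lists, at percentile 5.46, inside the band.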

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

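The alternatives with wider WT peaks, RefSeq assignment, promoter peaks left out and the leading member left out were chosen after the results were seen. No paired analysis was possible because each group has 1 library, and no replicate could be left out for the same reason. The planned motif search and its alternatives were not run. Depth limits every count of peaks, since a peak missing from the cKO list may have fallen below the caller's threshold. A common score minimum at the WT median left 17220 WT and 6459 cKO peaks by construction, and merging or autosomes alone changed neither count by more than 1.5 times. The share of WT peaks with a cKO partner was 55.5% with the stricter overlap, 57.0% above the median score of each list, 83.0% with equal numbers and 60.9% among WT peaks as wide as the narrowest cKO peak. The share of cKO peaks with a WT partner was 96.9%, 99.4% and 83.0% under the first 3 of these. The setting above the median scores keeps the ratio of the list lengths, so the shorter cKO list still limits its WT share. Only the setting with equal numbers removes that limit. The promoter gap before matching on score stayed positive, at 34.4 points above the median scores, 18.9 with equal numbers, 38.3 with promoters within 1 kb and 31.3 among the wider WT peaks. The smaller gaps within score bins and within score and width bins were not taken under the alternatives. Genes with a promoter peak in WT alone numbered 1006 with equal numbers, and those in cKO alone 98 above the median scores and 899 with equal numbers. The number of lists outside the band was 1 above the median scores, 1 with equal numbers, 0 within 10 kb of the TSS, 7 with matching on peak number only and 1 without the member with most WT peaks. With RefSeq assignment the number was again 2, but the cell cycle list (percentile 99.1) took the place of the genes silent in lymphocytes (5.36). Fewer peaks explain the lower numbers in part by construction, and elsewhere the cause was not tested. The naive and central list was above the band in 9 of 10 alternatives (percentiles 97.4 to 100), and the list of genes silent in lymphocytes below it in 5 of 10 (0.035 to 12.7). In the other 27 combinations these main results moved by no more than their interval or 1.5 times. Among single lists and core genes, 223 values were the same, 13 moved (9 of them core genes above the median scores), 6 became stronger and 6 weaker.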

Other observations

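All tests of explanations in this part were chosen after the results they bear on had been seen, and so were the gene families and the list of activation markers. Of 18 families formed from the gene descriptions, kinases shared 716 of 1119 WT peaks with the cKO list (64.0%, 61.1 to 66.7, percentile 99.96 of matched random lists), zinc finger proteins 281 of 395 (71.1%, percentile 98.6) and T cell receptor beta genes 14 of 19 (73.7%, percentile 99.9), the last at a single locus. Peaks of like score and class gave 61.0% for kinases, just below their interval, 69.6% for zinc finger proteins, inside theirs (66.5 to 75.4), and 44.7% for T cell receptor beta genes, below theirs (51.2 to 88.2). Predicted genes shared 4281 of 9308 peaks (46.0%, 45.0 to 47.0), below all of their random lists, but peaks of like score and class gave 46.3%, inside that interval. The other 14 families lay inside the band, among them interleukins and their receptors (55.6%), chemokines and their receptors (54.0%), solute carriers (57.9%), CD antigens (59.0%), tRNA enzymes (78.0%) and olfactory receptors (29.4% of 34 peaks).

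Both lists held peaks at places where reads from repeats are known to pile up. The strongest peak in each was at the predicted gene Gm10800 on chromosome 2, with scores of 19585 and 14103 against list medians of 28.1 and 16.6, followed in each by Gm10717 and Gm10722 near the start of chromosome 9. The strongest WT peaks without a cKO partner were also at predicted models, ahead of Gtpbp4. They were Gm33838 (score 4037), Gm11668 (694), Gm25352 (437) and Gm11168 (321), and they count among the 58 strong unshared peaks. This Gm11168 peak, on chromosome 9 at 3003346 to 3004233, lay between the peaks at Gm10722 and Gm10717. In these female mice the WT list held 8 peaks and the cKO list 9 on chromosome Y, at Mid1-ps1, Gm21860, Gm47283 and Gm21742, all between 90738030 and 90813118, at the end of the chromosome that borders and includes sequence shared with X.

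Strong WT peaks without a cKO partner were narrower than those with one, with median widths of 683 and 1287 bp. Of 9 such strong peaks below 465 bp 8 lacked a partner, of 14 between 465 and 550 bp 7, of 59 between 551 and 650 bp 10, of 369 between 651 and 850 bp 19, and of 6437 above 850 bp 14. A score cutoff alone, at lower depth, would leave partners close to the cutoff, but the lowest of 10 cKO score bins held 0 partners of WT score bin 10 (17 unshared peaks) and 0 of bin 9 (41 unshared peaks), and the 1st percentile of partner scores was 28.2 and 12.8 against a list minimum of 1.34, which argues against it in both. A candidate explanation is a larger minimum peak width in the cKO list, because the width ratios of wider shared peaks predict 46.9 to 55.7 peaks below that minimum and 58 were missing (counting interval 44.0 to 75.0). Only this total was compared, not its split by width. The 14 unshared peaks above 850 bp would have to be called much narrower in the cKO list. Loss of opening in the knockout stays untested for the single sites, Aars2, Rrbp1 and Art2b among them.

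The cKO list was shorter and lay largely inside the WT list. Of WT peaks at least as wide as the narrowest cKO peak 60.9% (60.4 to 61.5) had a partner, which does not settle how much the larger minimum width contributes, since wider WT peaks can be called narrower in the cKO list. Lower depth or enrichment of the cKO library may give such nesting, with 97.6% of cKO peaks shared, and a general loss of accessibility in the knockout predicts the same. With 1 library per group and no read totals these cannot be told apart.

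Genes of the naive and central T cell state had cKO partners more often than matched genes (71.8%, 63.0 to 79.2). Peak strength, class and width argue for 56.4%, below that interval, and no single member carried the result, since the percentile with any 1 member left out was at least 99.8. A hypothesis is that the cKO library held fewer activated and more resting Treg cells. A list of 40 activated and tissue Treg markers, 19 of them also in the Treg identity list, shared 73 of 156 WT peaks (46.8%, 39.1 to 54.6), at percentile 13.5, inside its band, and like peaks gave 50.9% to 51.2%, so it does not decide. The 9 members with no shared peak, among them Klrg1, Il1rl1, Havcr2 and Fgl2, had WT peaks scoring at most 32.3, and a shift in cell state and a genotype effect within cells stay open for the naive and central list.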
